A study of Drosophila melanogaster with 2 samples.

How the data were processed

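Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos collected 0 to 24 h after egg laying. The flies carried a transgene that fuses danr (distal antenna-related) to eGFP, and the fusion protein was pulled down with an antibody against GFP, per the labels. Chromatin was sheared by sonication, with a stated size range of 200 to 800. The labels give 2 biological replicates, each with 1 technical replicate, in 1 group. No treated group, second genotype or second stage was part of the series. The labels name control libraries, which were not analysed here, so no background was measured from them here. Whether the authors' peak calls and signals already draw on those libraries was not checked.

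The deposited files were 8 peak lists in dm6 coordinates, per the file headers and labels. For each replicate there was a ranked list and a thresholded list, and for both replicates together there were 2 ranked lists, a thresholded list and a conservative thresholded list. The peak caller, the aligner and their versions are not given in the sources used here. The score of each deposited peak is a transform of its irreproducible discovery rate (IDR), a measure of how well the rank of a peak repeats between 2 sets of reads, and all deposited thresholded rows had a score of at least 830, which stands for an IDR of 0.010. The signal of each deposited peak is the authors' own enrichment value at that peak, and it was used only to describe, rank and filter peaks within a list or to correlate replicates. The deposited ranked lists also hold the −log10 of the IDR per peak, which was used only to check the score. Reads per library are not part of these lists, so the depth is unknown and no interval from read counts was computed.

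Which ranked list gave which thresholded list was checked by exact coordinates, and every thresholded row was found in its source. In 1 of the 2 ranked lists of the whole series, rows pair a peak of replicate 1 with a peak of replicate 2, as far as could be checked. Both members were found by exact coordinates in the ranked lists of the replicates for 46526 of its 120578 rows, and for 1 row of the other list. These 46526 rows gave the signal in each replicate for the correlation. For the other rows of that list the pairing was not shown. Of the 2911 rows of the pooled ranked list with a score of at least 830, 112 were missing from the thresholded list. The files' descriptions name 1 further input to the thresholded lists that the ranked lists lack. Its content is not described there and it was not analysed here, so whether it is a list of excluded regions is unknown.

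Rows of 1 list that overlapped by at least 1 bp were merged to a region, and the row of highest signal gave its summit and its signal. Regions on the 7 chromosomes 2L, 2R, 3L, 3R, 4, X and Y were annotated with the Ensembl release 115 gene set, whose assembly has the same sequence as dm6, and every peak ended within its reference chromosome. Transposable element entries were left out. A summit within 500 bp of any annotated start site was called promoter, and the other summits were called distal. The remaining classes were taken in the order 5' UTR, CDS, 3' UTR, other exon, intron and intergenic. Random expectation came from 1000 placements of as many points on the same chromosome outside assembly gaps, with a two-sided permutation test unless stated. The overlap of replicates was tested one-sided against 1000 random placements of the regions of the other replicate, with 1 bp as the overlap in every setting. Chromosomes were tested with a two-sided exact binomial test against sequence length. The difference in median signal was tested with a two-sided permutation test of 100000 resamples.

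A gene was counted as bound if a summit lay within 1000 bp of any of its start sites. Gene lists (19) and motifs (20) were fixed before the data were examined, as were the groups, the tests and most of the alternatives. Lists were tested with Fisher's exact test, two-sided, against the other protein-coding genes, or against all other annotated genes for tRNA genes, with Benjamini-Hochberg adjustment over the lists. Beside it, 10000 random gene sets of the same size were drawn within deciles of gene length (10 bins), one-sided towards more bound genes. Motifs and all possible 6-mers, with reverse complements joined, were counted once per window of 50 bp either side of the summit and compared with the windows 1000 bp to the left and right, with Fisher's exact test, two-sided, and Benjamini-Hochberg adjustment. Neighbouring bases make 6-mers overlap, so their tests are not independent of each other.

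The rule for named genes, also fixed beforehand, took danr and its paralog dan, the genes with the start site nearest to the 10 regions of highest signal, up to 4 bound members of each list by signal, the 5 protein-coding genes with the most regions from 5 kb upstream to the gene end, all fixed motifs, and the 10 6-mers of smallest adjusted p among those higher at the summit. Genes named outside this rule are stated as such. Alternatives were the conservative list, the regions above the median signal, the list of each replicate alone, other promoter widths, other ways to assign summits to genes, other overlap criteria, other windows and other backgrounds. Leaving out replicate 1 means using the thresholded list of replicate 2 alone, and the reverse. Alternatives chosen after seeing the data were placements matched on A+T content in bins of 5%, 6-mers against 2 dinucleotide-preserving shuffles of each window (with 10 further shuffles tested in place of the summits), 6-mers at distal summits, and the omitted regions put back.

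The tests were tried on simulated data. A 6-mer planted in 10.0% of 2600 random windows came out first of all 6-mers, among 10 called higher, of which 2 shared no 4 bases with it, and no 6-mer was called with nothing planted. A gene list bound at a known raised share was called in 20 of 20 draws, and 0 of 380 list tests were called with random bound genes. An overlap made to be 64.3% was measured as 64.8%. Random summits gave a promoter p under 0.05 in 1 of 20 draws. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.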

Results

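The data are the peak lists of a ChIP-seq experiment on danr, a gene named distal antenna-related that encodes a nuclear protein with a pipsqueak-type DNA-binding domain, tagged with eGFP and expressed in whole embryos aged 0 to 24 h. The 2 biological replicates form 1 group, so the design asks where on the genome the tagged protein was recovered and how far the replicates repeat each other. The thresholded list of the whole series held 2799 peaks, which merged to 2653 regions covering 904 kb. Of these regions, 2632 lay on chromosomes 2L, 2R, 3L, 3R, 4, X and Y and 21 on other scaffolds. The median signal, the authors' enrichment value, was 82.8, with 1 in 10 regions below 53.0 and 1 in 10 above 215. Replicate 1 alone gave 1637 regions with a median signal of 58.0, and replicate 2 alone gave 1604 regions with a median of 57.8. Sequencing depth is unknown from these lists.

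Most of the 10 strongest regions had their summit in a promoter. The region of highest signal, 1356, was on X from 2703732 to 2704042, with its summit 30 bp from the start of Ugalt (FBgn0024994), which encodes a UDP-galactose transporter. The signal there was 701 in replicate 1 and 648 in replicate 2. The next was in an intron of CG11050 (FBgn0031836) on 2L from 6612547 to 6612883, 1016 bp from the start site, with a signal of 1304. CG14100 (FBgn0036889) followed with 1152 on 3L from 19590460 to 19590770, and mRpL41 (FBgn0034001), a mitochondrial ribosomal protein gene, with 984 on 2R from 15217602 to 15217905, both in the promoter. The Polycomb group gene ph-p (FBgn0004861) had a promoter region with a signal of 937 on X from 2137203 to 2137505. The remaining regions of the top 10 had signals from 798 to 866 and were nearest to the start sites of CIA30, a complex I assembly factor, HmgZ, an HMG-box chromatin protein, PNPase, Adf1, a transcription factor, and Art3. The summits at HmgZ and Adf1 were intronic, and the other 3 were promoter summits. All 10 regions had the top score of 1000 in each replicate's ranked list.

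The replicates shared most of their regions, and the strong ones almost all. Of the 1637 regions of replicate 1, 1063 overlapped a region of replicate 2, which is 64.9% (95% exact binomial interval 62.6 to 67.2%). Of the 1604 regions of replicate 2, 66.3% (63.9 to 68.6%) overlapped one of replicate 1. Random placement gave 0.743% and 0.789% on average (one-sided permutation p = 0.001 for each, the smallest that 1000 placements can give). Among the 409 strongest regions of replicate 1, 95.6% had a partner, as did 95.5% of the 401 strongest of replicate 2. Among the weakest 410 and 401 the share was 35.9% in each. In the series list, 1058 of the 2653 regions were in both replicates' thresholded lists, with a median signal of 143, and 663 were in neither, with a median of 56.7.

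Signal ranks followed each other loosely over all rows with both peaks found and more closely among those past the threshold. Across the 46526 rows with both peaks found, Spearman's rho was 0.27 and Pearson's r of log2 signal was 0.41, and 70.4% had signals within 2-fold. Across the 2156 of these rows in the conservative list, rho was 0.66 and r was 0.78, and 92.9% were within 2-fold. Some peaks occur in more than 1 of the 46526 rows, so the number of distinct peaks is lower. That list is selected on IDR, which measures how well ranks repeat, so its higher rho is no independent measure of reproducibility. These are correlations across peaks, which are not independent replicates, so no p-value is given. The conservative list had 2088 regions and overlapped 1974 regions of the series list, 74.4% of them. Regions outside it had a median signal of 55.7, against 97.7 for those inside it.

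**Figure D1:**
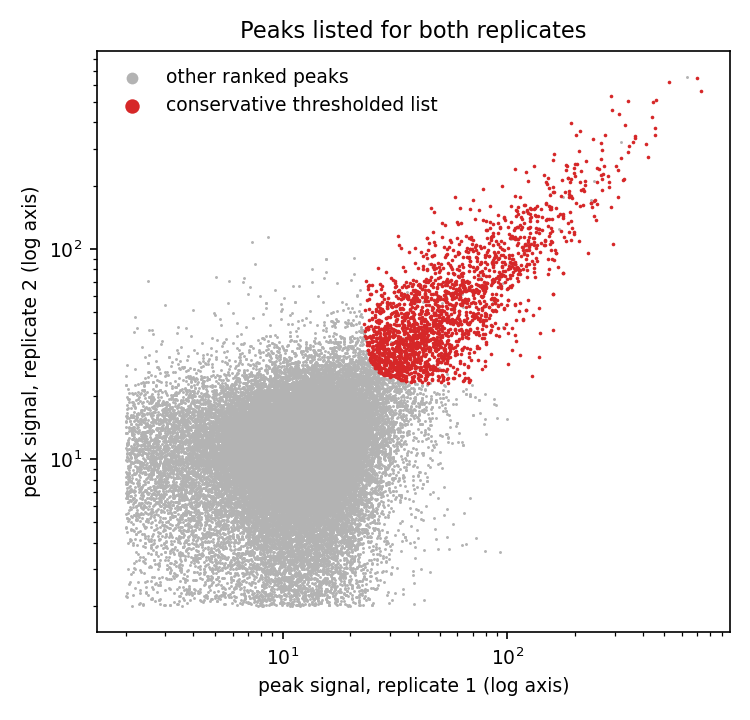
Signal of each row whose 2 peaks were found in the ranked lists of the replicates, replicate 1 on the horizontal and replicate 2 on the vertical axis. Both are log scales without unit. The 2156 rows of the conservative list (red) form a band with rho 0.66, and the remaining rows (grey) form a cloud at low signal.

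Summits per Mb were highest on X and very low on chromosomes 4 and Y. X carried 533 summits, or 22.6 per Mb, which was 1.18 times the share of its length (two-sided exact binomial test, adjusted p = 7.1e-05). The binomial test treats each summit as an independent draw. Regions lay closer together than random placements, as given below, so its p-values may be too small. Chromosome 4, the small and largely heterochromatic autosome, carried 6 (0.233 times, exact adjusted p = 2.2e-05) and Y carried 1 (0.0143 times, 95% exact interval 0.00036 to 0.079, exact adjusted p = 1.1e-28). Their shares varied with the list but passed in each. Chromosome 4 was at 0.312 times in replicate 1 alone (5 summits), 0.0657 times in replicate 2 alone (1 summit, interval 0.0017 to 0.37) and 0.0489 times in the conservative list (1 summit, interval 0.0012 to 0.27), and Y had 0, 3 (0.0724 times, interval 0.015 to 0.21) and 0 summits. The arms 2L, 2R, 3L and 3R had between 17.9 and 20.4 summits per Mb, and none of them passed the threshold. In replicate 1 alone 2L passed as higher (1.16 times) and 3R as lower (0.885 times), with neither passing in replicate 2 alone (1.08 and 0.946 times). Sequence length stands in for the length to which reads can be mapped, which is shorter on repeat-rich chromosomes such as 4 and Y. Mapping is not the only limit for chromosome 4. Its ranked peaks of any score were 676 of 73075 in replicate 1 (0.925%) and 35 of 99556 in replicate 2 (0.035%). The pooled count there therefore joins 2 libraries that differ widely.

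Promoters held the largest share of the regions, and coding sequence held very few. A summit within 500 bp of a start site was found for 1224 of 2632 regions, 46.5% (95% exact binomial interval 44.6 to 48.4%). Random placements gave 13.6% on average and 15.6% at most (two-sided permutation p = 0.002, the smallest that they can give). Among the 131944 ranked peaks below the score limit, 14.9% were at promoters (odds ratio 4.98, Fisher's exact test, two-sided, p = 8.6e-316). These peaks were counted as rows without merging, unlike the regions. Fisher's exact test treats each row and region as an independent draw, so its p-value may be too small. Summits in coding sequence made up 1.06% against 13.7% at random, and those in 3' UTRs 0.456% against 4.47%. Introns held 37.3% of the summits against 39.5%, and intergenic sequence 13.5% against 27.2%. The adjusted permutation p was 0.0035 for coding sequence, 3' UTRs and intergenic sequence and 0.025 for introns, while 5' UTRs (0.532% against 0.795%, adjusted p = 0.15) and other exons (0.684% against 0.814%, adjusted p = 0.55) did not pass. With random placements matched on the A+T content of the window, chosen after seeing the data, the expected share of coding sequence was 4.75% and that of promoters 13.5%.

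**Figure D2:**
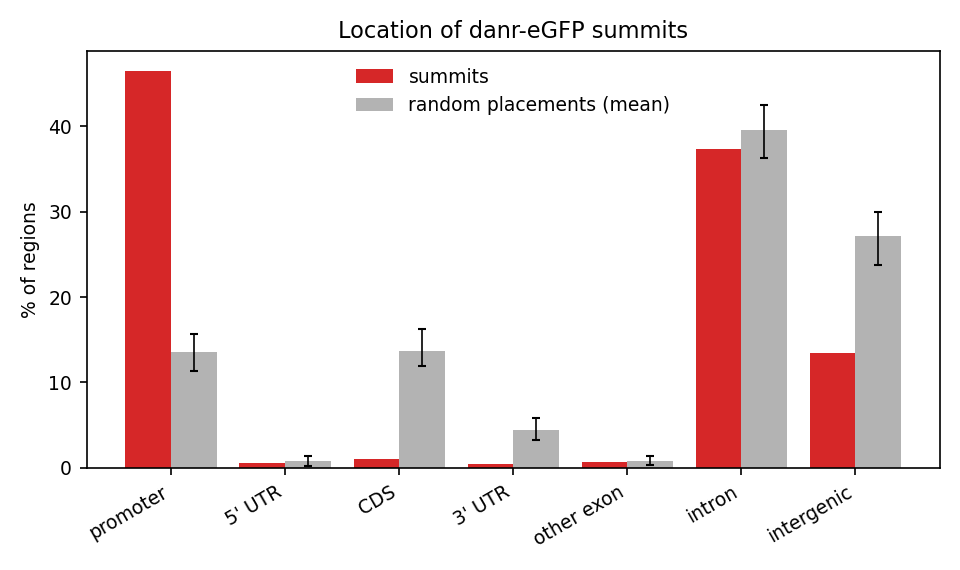
Share of the 2632 regions (%) whose summit lies in each class of location (red), beside the mean of 1000 random placements (grey) with bars from their lowest to their highest value. Promoters hold 46.5% of the summits against 13.6% at random, and coding sequence 1.06% against 13.7%.

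Promoter regions were also the stronger ones. Their median signal was 91.2 (quartiles 66.3 to 156) against 77.2 (59.9 to 113) for distal regions. The difference of 14.0 had a permutation p of 1e-05, the smallest that 100000 resamples can give (two-sided). It was 7.55 in replicate 1 alone and 14.0 in replicate 2 alone, and passed in both. The ranges overlapped widely, and strong distal regions such as that in CG11050 were among the first 10.

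At the tagged gene itself the signal was low. danr (FBgn0039283) lies on 3R from 25138072 to 25139903, and dan (FBgn0039286), its paralog, from 25184383 to 25192806 on the same strand. A region from 25137930 to 25138273 had its summit 30 bp inside danr, with a signal of 50.5 and rank 2499 of 2653. It was in neither replicate's thresholded list, with a signal of 34.8 in replicate 1 and 16.1 in replicate 2. Between the paralogs there were 4 more regions, with signals of 67.7, 47.8, 84.5 and 49.8. The strongest, from 25178578 to 25178921, lay 5633 bp upstream of dan and was the only one of the 5 in the conservative list. Nothing past the threshold lay within dan. The tagged copy of danr can add reads at its own locus, so these values are not a measure of binding alone.

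**Figure D3:**
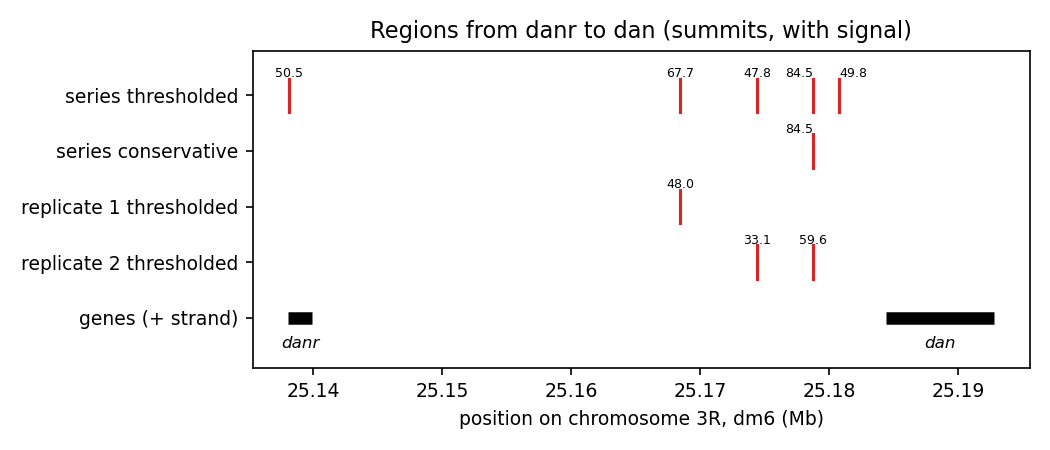
Regions of the 4 thresholded lists from danr to dan on 3R (dm6, Mb), each drawn as a line at its summit with its signal above it, and the genes as black bars. The strongest region, at 84.5, lies upstream of dan, and the region at the start of danr has a signal of 50.5.

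Ribosomal protein genes were bound far more often than other genes. Of 13968 protein-coding genes, 1873, or 13.4%, had a summit within 1000 bp of a start site. Of 92 ribosomal protein genes, 38 did, which is 41.3% against 13.2% of the other genes (odds ratio 4.62, Fisher's exact test, adjusted p = 5.9e-10). In replicate 1 alone the share was 28.3% (odds ratio 4.15) and in replicate 2 alone 19.6% (odds ratio 2.45), from fewer regions, and the list passed in both. Genes of matched length gave 9.81% (one-sided permutation, 1e-04, the smallest that 10000 sets can give). The strongest were at RpL34b with a signal of 222, RpL32 with 217, RpS27 with 149 and RpL7 with 148, all within 146 bp of the start site. Heat shock genes had 5 of 15 members bound, or 33.3%, which did not pass (Fisher's exact test, adjusted p = 0.11), with Hsp27, a small heat shock protein gene, at a signal of 358, stv at 152, Hsp22 at 107 and Hsp83 at 96.1. In replicate 1 alone the heat shock list did pass, at the same 33.3% (Fisher's exact test, adjusted p = 0.024), but not in replicate 2 alone, at 26.7% (adjusted p = 0.13).

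Chemoreceptor, cuticle protein, histone and tRNA genes were bound less often than other genes. Of 179 chemoreceptor genes only Or88a was bound (0.559%, Fisher's exact test, adjusted p = 2.7e-09), of 95 cuticle protein genes only Cpr65Ay and Cpr73D (2.11%, adjusted p = 0.00085), and of 111 histone genes none (0%, exact upper bound 3.27%, adjusted p = 1.0e-06). The summits counted for Or88a, Cpr65Ay and Cpr73D lay 648, 823 and 704 bp from the start site. All were promoter summits, so a start site of another gene lay closer, and that at Cpr73D also lay within Ogdh. Counting only summits within 500 bp, no chemoreceptor or cuticle protein gene was bound. Of 290 tRNA genes 12 were bound, or 4.14% against 11.7% of all other annotated genes (Fisher's exact test, adjusted p = 5.3e-05), with the neighbours tRNA:Tyr-GTA-1-7 and tRNA:Tyr-GTA-1-8 sharing 1 region at 193, tRNA:Val-TAC-1-1 at 143 and tRNA:Phe-GAA-1-2 at 97.2. The summit of the shared region lay within CG8036 and p, and that counted for tRNA:Val-TAC-1-1 lay within lama, 839 bp from the start site. Genes matched on length gave 12% for chemoreceptor, 9.57% for cuticle protein, 5.26% for histone and 4.70% for tRNA genes, so the tRNA share was near that of other short genes. In replicates 1 and 2 alone, 1.72% and 2.07% of tRNA genes and 1.05% of cuticle protein genes (in each) were bound, and the 4 lists passed in both. Histone and tRNA genes occur in near-identical copies, where peaks can be lost if reads are not placed. Fisher's exact test and the exact bound count each copy as an independent gene, so for these genes they can overstate the evidence.

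The 13 lists of developmental, cell type and cell cycle genes did not pass in either direction, with adjusted p from 0.083 for segmentation genes to 1 (Fisher's exact test). None of 28 segmentation genes was bound (exact upper bound 12.3%), none of 20 neuroblast temporal and fate genes (16.8%) and none of 8 homeotic genes (36.9%). Of 22 eye and antenna genes, 2 were bound (9.09%), namely Dll, the appendage selector gene, at a signal of 134, with no ranked peak overlapping in replicate 2, and danr itself at 50.5. In replicate 1 alone the share was 4.55%, and in replicate 2 alone no gene of the list was bound. The Notch and proneural list had 3 of 19 (15.8%), with numb at 236, E(spl)m3-HLH at 156 and E(spl)mdelta-HLH at 117. Neuron differentiation genes had 1 of 16 (6.25%), elav, the neuronal RNA-binding protein gene, at 361. Glia genes had 3 of 12 (25%), moody at 290, Gs2 at 165 and pnt at 58.0. The summits counted for E(spl)mdelta-HLH, elav and moody lay within other genes, CG43116, arg and CG4313, at 961, 277 and 167 bp from the start site. Which gene of each pair they belong to cannot be told from position.

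The other 6 of these lists were bound at shares from 10% to 22.2%, with wide intervals. Mesoderm and muscle genes had 2 of 20 (10%), tin at 174 and stumps at 91.2, and gut and fat body genes 2 of 12 (16.7%), bowl at 221 and fkh at 94.9. Tracheal genes had 1 of 9 (11.1%), trh at 123. Ecdysone response genes had 4 of 18 (22.2%), E23 at 376, Eip75B at 172, usp at 81.7 and Hr78 at 72.2. With the nearest start site at any distance, 61.1% of the ecdysone list were counted (Fisher's exact test, adjusted p = 2.1e-05), and with 5 kb upstream to the gene end, 72.2% (adjusted p = 0.00011). Under these assignments the mesoderm and muscle list also passed, at 40% (adjusted p = 0.011, Fisher's exact test) and 50% (adjusted p = 0.040), and under the first so did the homeotic list, at 50% (adjusted p = 0.042). Against genes of matched length none of these lists passed after adjustment over the lists. The adjusted permutation p (one-sided) was 0.0503 and 0.0532 for the ecdysone list and 0.34 and 0.59 for the mesoderm and muscle list. For the homeotic list under the first assignment it was 0.64. Germline genes had 2 of 13 (15.4%), bgcn at 102 and nanos at 54.3, and cell cycle genes 2 of 15 (13.3%), CycE at 93.0, with no ranked peak overlapping in replicate 2, and fzr at 45.6. The summits counted for nanos and fzr lay within other genes, CG11779 and Pp2C1. In replicate 2 alone no cell cycle gene was bound, and the ecdysone list was at 11.1% and the gut and fat body list at 8.33%. In replicate 1 alone the mesoderm and muscle list was at 5% and the cell cycle list at 6.67%.

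**Figure D4:**
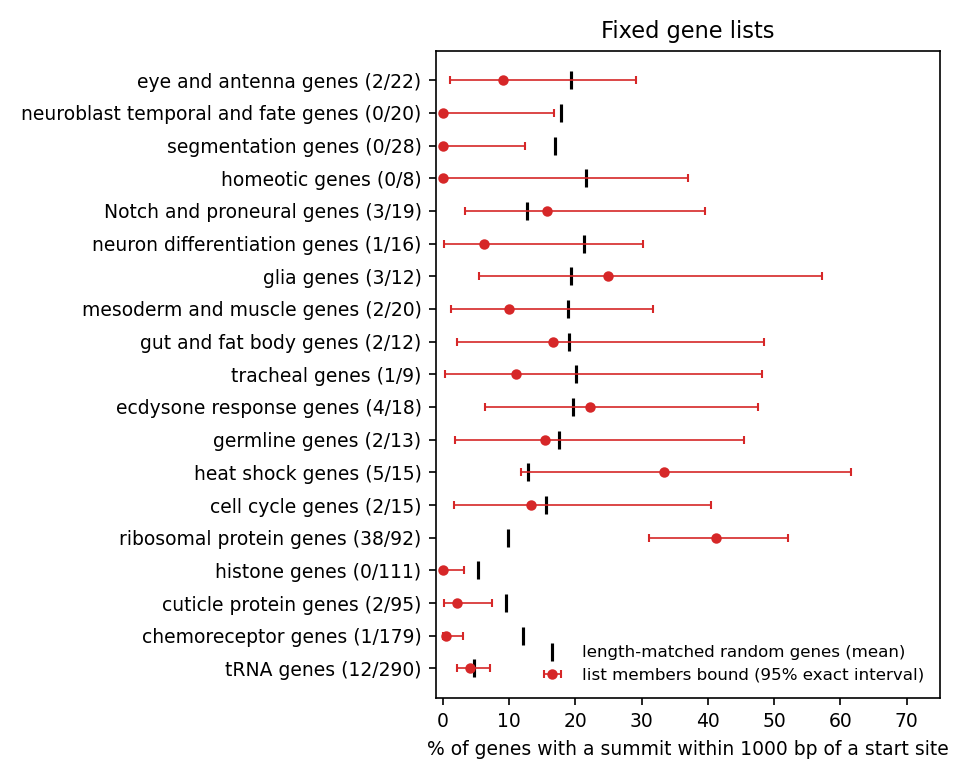
Share of the members of each of the 19 fixed gene lists with a summit within 1000 bp of a start site (%, red points with 95% exact binomial intervals), beside the mean of length-matched random genes (black ticks). Ribosomal protein genes, at 41.3%, stand above their tick at 9.81%, and chemoreceptor genes, at 0.559%, below theirs at 12%.

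Summits were rich in A and T and carried TATA-like sequence. The mean A+T content of the window of 50 bp either side of the summit was 66.8% ± 9.37 (SD over 2632 windows), against 57.7% ± 10.6 in the flanking windows and 53.6% ± 9.80 at ranked peaks below the limit. TATAAA, the TATA box core, was in 23.2% of summit windows and 11.9% of flanks (odds ratio 2.25, Fisher's exact test, adjusted p = 3.3e-36). TATCGATA, the site of the replication-related element factor DREF, was in 0.988% against 0.171% (odds ratio 5.83, Fisher's exact test, adjusted p = 4.2e-06). The homeodomain core TAATTA was in 9.50% against 5.93% (Fisher's exact test, adjusted p = 8.5e-08), the Sox core ACAAT in 30.9% against 25.9% (adjusted p = 7.2e-06), the A tract in 8.81% against 5.76% (adjusted p = 1.9e-06) and the Twist-type E-box CATATG in 4.41% against 3.31% (adjusted p = 0.029). Of these 6 motifs, 3 did not pass in every list. DREF had an odds ratio of 2.90 in replicate 2 alone and of 2.23 in replicate 1 alone, where it did not pass. The A tract did not pass in replicate 1 alone (odds ratio 1.29), and the Twist-type E-box did not pass in replicate 1 alone (1.37), in replicate 2 alone (1.19), in the conservative list (4.12% against 3.21%) or in the regions above the median signal (3.95% against 3.23%).

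Several G- and C-containing motifs were rarer at summits than in the flanks. The general E-box was in 33.8% against 41.3% (Fisher's exact test, adjusted p = 1.1e-09), the Pho core GCCAT in 13.4% against 18.1% (adjusted p = 5.6e-07), GAGAG, the GAGA factor site, in 9.08% against 12.2% (adjusted p = 7.7e-05), the Snail-type E-box CAGGTG in 2.32% against 4.03% (adjusted p = 0.00013) and the CA repeat in 0.874% against 2.49% (adjusted p = 9.8e-07). In replicate 2 alone the CA repeat was in 0.386% against 2.93%. With windows of 100 bp either side GAGAG did not pass (21.5% against 22.3%). The sites of Zelda (0.532% in both sets), GATA (5.17% in both sets), M1BP (0.152% against 0.133%), AP-1 (0.760% against 1.10%), Su(H) (4.98% against 5.87%), Grainy head (0.114% against 0.171%), POU (1.94% against 1.58%), BEAF-32 (13.1% against 11.6%) and Tramtrack (0.912% against 1.01%) did not pass. BEAF-32 passed as higher with windows of 100 bp either side (25.3% against 21.7%), against peaks below the limit (13.1% against 10.6%) and against shuffled windows (13.1% against 9.92%). It lay below the flanks in replicate 1 alone (11.3% against 12.2%) and in the regions above the median signal (11.1% against 11.9%), where POU passed as higher (2.36% against 1.37%). Of these motifs, those with few sites varied between the replicates without passing. In replicates 1 and 2 alone Tramtrack was in 0.489% against 1.07% and 1.03% against 0.869%, Zelda in 0.305% against 0.580% and 0.257% against 0.483%, M1BP in 0.122% against 0.183% and 0.257% against 0.161%, AP-1 in 0.916% against 0.947% and 0.965% against 0.933%, and Grainy head in 0.122% in both sets and 0.129% against 0.0965%. Against shuffled copies of the summit windows with the same dinucleotide counts, DREF, the A tract and the Twist-type E-box still passed as higher. The TATA box did not (23.2% against 22.7%, Fisher's exact test, adjusted p = 0.73), and the homeodomain core was lower at summits (9.50% against 12.5%, adjusted p = 0.0039), as was the Sox core (30.9% against 34.5%, adjusted p = 0.016). In that comparison GAGAG was higher (9.08% against 6.72%, Fisher's exact test, adjusted p = 0.0072), as were the general E-box (33.8% against 29.9%, adjusted p = 0.0085), Su(H) (4.98% against 3.46%) and the CA repeat (0.874% against 0.342%).

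Of all 6-mers, 406 were more frequent at summits and 933 less frequent. All 36 6-mers made of A and T alone were among the 406. The 10 of smallest adjusted p were TTAAAA, AAATAT, ATATTA, AAAATA, ATTTTA, TATTAA, AATATA, TAAAAA, ATTTAA and TAAATA, with odds ratios from 2.38 to 3.01. TTAAAA was in 34.8% of summit windows and 15.6% of flanks (Fisher's exact test, adjusted p = 7.9e-78), and AAATAT in 34.9% and 16.3% (adjusted p = 1.6e-71). Against dinucleotide-shuffled windows, chosen after seeing the data, 128 6-mers were higher and 142 lower. Of the 128, 56 were also among the 406, and 31 were among the 933. Of the 36 made of A and T alone, 9 were higher and 10 lower.

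**Figure D5:**
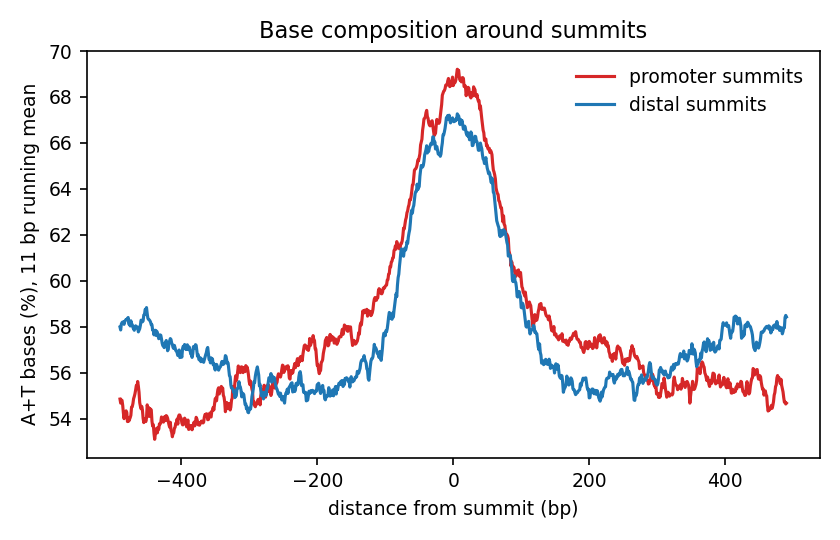
Share of A and T bases (%, 11 bp running mean) by distance from the summit (bp), for promoter summits (red) and distal summits (blue). Both lines rise towards the summit, where the mean over 50 bp on either side is 67.7% for promoter and 66.1% for distal summits.

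Regions lay closer together than uniform random placements and gathered over some genes. The placements were not matched on promoters, which held 46.5% of the summits against 13.6% at random. These tests therefore cannot tell a clustering of binding from the layout of promoters along the chromosomes. The median distance to the nearest other region was 8271 bp, against a mean of 17510 bp in random placements (two-sided permutation p = 0.002, the smallest they can give). In replicate 1 alone it was 13984 bp against 28093 bp and in replicate 2 alone 15284 bp against 29661 bp. Among protein-coding genes, 192 held at least 3 regions from 5 kb upstream to their end, against 131 at random (permutation p = 0.002, again the smallest). CG1677 (FBgn0029941, X, 7281089 to 7405797) and kirre (FBgn0028369, X, 2740384 to 3134532), an adhesion molecule gene of muscle founder cells, held 11 regions each. CHES-1-like, a forkhead-type transcription factor gene, and sbb, also known as scribbler, held 10 each, and Tlk, the Tousled-like kinase gene, held 9. All but sbb are on X. These genes were ranked by count alone, without regard to their length or to the higher density of summits on X. A long gene such as kirre can hold many regions through its length alone. Whether any single named gene held more regions than random placements give was not tested. The excess of genes with at least 3 regions passed in replicate 1 alone (86 against 53.8 at random). It did not pass in replicate 2 alone (59 against 48.4 at random, permutation p = 0.092) or in the regions above the median signal (43 against 35.1, p = 0.15).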

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

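The tests of 6-mers against shuffled windows and in distal summits were chosen only after the result was seen. So were those of gene length and of summits elsewhere in the joined developmental genes. The tests of list length and of signal for the chromosome 4 peaks were also chosen afterwards. The length-matched draws for ribosomal protein and tRNA genes were planned as list tests, and only their use to weigh explanations was chosen afterwards. Some strong regions stand outside the thresholded list on which the report rests. The pooled ranked list holds 106 merged regions that pass the score limit and are left out of the thresholded list, 76 of them on the 7 chromosomes. As a set they are somewhat weaker than the regions kept, with a median signal of 74.5 against 82.8, and 7 are among the top 100. The thresholded lists have 1 further input that was not analysed here, and if it lists regions to exclude, these omissions were made on purpose and their signals are not a measure of binding. The strongest, on 2L from 480928 to 481243 and 1403 bp from a start site of cbt, has a signal of 1278, rank 3 among all regions past the limit, with 628 in replicate 1 and 657 in replicate 2. Others lie near Lk6 (640), larp (455) and trx (357). Of the 112 omitted rows, 42 are on 3R, 20 on 2L and 33 on other scaffolds. These genes were chosen after their values were seen. Putting the regions back gives a promoter share of 46.1% and 42.4% of ribosomal protein genes bound.

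The A+T-rich 6-mers at summits may come from base composition alone or from core promoter elements. Against windows shuffled with their dinucleotide counts kept, 9 of the 36 6-mers made of A and T alone are higher and 10 lower, while in 10 further shuffles 0 were higher. These 9 are thus more frequent than the dinucleotide counts of the summit windows give. The flanks were not compared with shuffled copies of their own, so whether this departure is particular to summits is unknown. Composition therefore stays open for all 36. Of the 10 named 6-mers, 5 pass as higher in this test (AAATAT, ATATTA, AAAATA, AATATA and TAAATA, largest adjusted p 0.0041), and the other 5 do not (smallest adjusted p 0.19). For the same reason composition stays open for all 10. In the 1408 distal summits the 36 have a median odds ratio of 1.75 (quartiles 1.47 to 2.01), and 35 of them are higher, which argues against core promoters as the only source. A sequence preference of the tagged protein is left open, and no biological explanation was tested because the design has 1 group.

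None of the 56 segmentation, neuroblast and homeotic genes has a promoter summit, while 38 of 92 ribosomal protein genes do (26 in replicate 1 alone and 18 in replicate 2 alone), and the 3 lists were joined because each was at 0, so no p-value is given for the joined set, and none of them passed alone. Gene length argues the other way, since length-matched sets give 17.8% on average, above the 13.4% of all protein-coding genes, and for ribosomal protein genes a share of 1e-04 of such sets hold as many, the smallest that 10000 sets can give. The omitted regions fall within 1000 bp of 0 of the 56 genes, which argues against these as the cause. Whether summits lie elsewhere in these genes stays open. From 5 kb upstream to the gene end 8 hold a summit, against 10.9 for length-matched genes that also lack a promoter summit (share with as many 0.881). With the nearest start site at any distance 25% of segmentation and 50% of homeotic genes are counted, against 19.2% and 34.8% of length-matched genes. Neuroblast genes go the other way, at 15% against 22.8%. Length-matched sets hold as many in shares of 0.28, 0.29 and 0.88 of draws, in the order given, so none of the 3 lists passes as higher. Whether strongly transcribed loci are recovered by any pull-down cannot be told apart from binding: tRNA genes show no excess (share 0.73), but reads from their repeated copies could have been discarded, and no control library was analysed here.

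Replicate 1 has 676 ranked peaks on chromosome 4 and replicate 2 has 35, a ratio of 0.0518, while all ranked peaks have a ratio of 1.36, which argues against the length of the list as the cause. The peaks of replicate 1 there are no weaker than its other ranked peaks, with a median signal of 11.6, or 1.04 times that of the others, but most of them lie below 18.4, the lowest signal of its thresholded list. Y goes the other way, with 7 and 329 rows, as do other scaffolds, with 272 and 2073. The number of copies of these chromosomes in the embryos and in the control libraries of each replicate was not tested, and no biological explanation was tested with 1 sample on each side.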

How the results depend on the processing

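The 6-mer alternatives with shuffled windows and distal summits, and the A+T-matched placements and restored regions, were chosen after seeing the data. The replicate overlap, the X excess, the promoter share and its signal difference, and the spacing of regions kept their direction and their side of the threshold under every alternative run, with promoter shares from 35.2% (250 bp) to 57.5% (1000 bp). The rank correlation moved from 0.27 to 0.66 in peaks past the threshold, which are selected on how well ranks repeat. By Fisher's exact test, lists with more bound genes numbered 1 as reported, 3 with 5 kb upstream to the gene end and 4 with the nearest start site. Against genes of matched length only the ribosomal protein list passed under each of these, after adjustment over the lists. With 5 kb upstream to the gene end, mesoderm and muscle genes turned to 50%, ecdysone response genes reached 72.2%, and homeotic (37.5%) and cell cycle genes (26.7%) crossed the level of other genes without passing. With the nearest start site, mesoderm and muscle genes (40%) and homeotic genes (50%) turned, ecdysone response genes reached 61.1%, and eye and antenna (27.3%), neuroblast (15%), segmentation (25%), tracheal (33.3%), cell cycle (33.3%) and germline genes (7.69%) crossed the level of other genes without passing. So did glia (8.33%) and cell cycle genes (13.3%) within 500 bp, tracheal (11.1%) and germline genes (7.69%) in the conservative list, and these and mesoderm and muscle genes (10%) in the regions above the median signal. Leaving out a replicate gave 1 to 2 lists with more bound genes, 3 (without replicate 2, where DREF, the A tract and the Twist-type E-box no longer passed) to 5 higher motifs and 59 to 86 genes with many regions. It gave 26.7 to 33.3% of heat shock genes, 8.33 to 16.7% of gut and fat body genes, 5 to 10% of mesoderm and muscle genes and 11.1% of tracheal genes. The regions above the median signal gave 43 genes with many regions, from fewer regions. Against dinucleotide-shuffled windows 2 motifs were lower, and the ratio of summit to background turned for GAGA factor (1.35), the general E-box (1.13), the Snail-type E-box (1.13), homeodomain (0.760), Pho core (1.07), CA repeat (2.56), Su(H) (1.44) and Sox (0.896). In 6-mers, 128 were higher and 142 lower against shuffled windows, and 476 were lower in distal summits. The cause was not tested except where fewer regions, a selection on IDR or a matched composition follow from the alternative itself. Reads per library are unknown, so what depth limits was not measured. No paired analysis was possible because the design has 1 group.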

Other observations

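Both hypotheses below were formed after the lists had been seen, and their tests were run on the same data. Among the 73 genes named as mitochondrial ribosomal proteins, 14 have a summit within 1000 bp of a start site, or 19.2%. They include mRpL41 with a signal of 984, mRpS10 with 798, mRpS23 with 662 and mRpL23 with 577, chosen after their values were seen. The mRpS10 region is also the one nearest to Art3. Length-matched genes give 7.63%, and a share of 0.001 of the random sets hold as many bound genes. That the tagged protein is recovered at these promoters more often than at those of other short genes is a hypothesis, and mRpL41 being in the top 10 prompted it.

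Promoter summits lie mostly just upstream of the start site, at a median of -122 bp, with 81.9% upstream. Start sites on both strands lie within 500 bp of 37.3% of the 1224 promoter summits. Whether summits lie at start sites on both strands more often than random promoter positions was tested by placing the same offsets at random protein-coding start sites, which give 27.7% on average and 31.9% at most (one-sided permutation p = 0.001, the smallest that 1000 draws can give). The summits may thus favour the space between divergent genes, as a hypothesis. The random start sites were not matched on how strongly the genes are transcribed.

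Against shuffled windows, the 6-mers that came directly after AAATAT by adjusted p hold a common core. CAGTGG is in 5.59% of summit windows and 1.69% of shuffled ones (odds ratio 3.44, Fisher's exact test, adjusted p = 3.7e-17), ACAGTG in 7.33% and 2.83% (odds ratio 2.72), CAGTGC in 6.80% and 2.74% (odds ratio 2.59) and CACTGA in 6.76% and 2.83% (odds ratio 2.49). Each contains CAGTG or its reverse complement. These 6-mers were chosen after their values were seen. The next in order, AAATGT, ATATAT, AATATT and AAAATA, lack the core. ACACTG, which follows them, holds it again (5.93% against 3.10%, odds ratio 1.97). How the CAGTG 6-mers compare with the flanks is not given here. Of the 128 6-mers higher than in shuffled windows, 56 were also higher than in the flanks and 31 were lower.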
